A study of Rattus norvegicus with 6 samples.

How the data were processed

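Gene expression was measured in bone marrow cells of male rats, 8 weeks old, cultured under osteogenic conditions with or without low-intensity pulsed ultrasound (LIPUS), a mechanical stimulus applied as short bursts of sound waves. Per the labels, 3 control samples and 3 LIPUS samples were taken on day 10, and Cy3-labelled RNA of each was put on 1 single-colour Agilent rat array. The labels do not say whether the replicates came from separate animals or separate cultures. P-values for single genes and for array means therefore measure only the spread between these samples.

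Each deposited spot table holds 45220 spots. Per the file headers, spot and local background brightness are given as intensity, as whole numbers up to the scanner limit of 65535, with no normalization. The deposited tables also give the share of pixels at that limit in percent, and signal-to-noise, position and spot quality as a score. The scanner, its gain and the software version are not given in the sources used here. A value table deposited by the authors holds processed values on a log2 scale. That scale was found from the values: the 75th percentile is 0 in every column and the column medians are −2.37, −2.48, −2.53, −2.49, −2.62 and −2.85, so higher values mean higher expression. Subtracting the column minimum and undoing the log2 gave whole numbers, within a tolerance of 0.01, for 98.7% to 98.9% of probes. Those whole numbers are lower than the intensities in the spot tables, so fewer probes reach the scanner limit there (29 to 93 per array above 90% of it). How the authors made the table stays unknown. The table was used as an alternative source of values, and for genes whose spots reach the scanner limit.

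The plan fixed before the data were examined assumed columns of Agilent's own software, a processed signal and a flag for signal well above background. The spot tables have neither. The processed signal was replaced by limma's normexp background correction of the spot median with the local background median (offset 50). The flag was replaced by a spot median minus background above the 95th percentile of the 153 negative control spots of the same array. Corrected values were put on the log2 scale, spots of 1 probe were averaged, and each array's 75th percentile over its gene probes was subtracted. The tables hold 43379 gene spots for 41012 probes, of which 263 probes have 10 spots each. Probes above the background limit on at least 3 of the 6 arrays were kept, which left 23257. Symbols came from matching the accession of each probe to a RefSeq table of assembly GRCr8, used for names only. Of 11145 probes with a curated RefSeq accession, 10692 matched, and of 4793 with a predicted RefSeq accession, 76 did. The 8830 probes with an Ensembl transcript and 16244 others carry no symbol in that table. The probe with the highest mean stood for each of the symbols, and probes without a symbol were tested on their own, which gave 21845 tested genes or probes, 5697 of them with a symbol.

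LIPUS and control were compared with limma (lmFit and eBayes, 3.58.1, in R 4.3.3), two-sided, with the group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are LIPUS minus control with the moderated standard error. A total of 33 gene lists with 906 symbols were written in advance, and 519 of those symbols were measured. Each list with at least 5 measured members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares the changes of a list's genes with those of other genes, so its p-value is no measure of the spread between samples. Camera with an estimated correlation and fry were run beside it. The mean of a list on each array was compared with an exact permutation test, two-sided, for which 3 arrays against 3 allow no p below 0.1. The number of arrays limits the precision. Labels were read with jsonlite 2.0.0, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

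Genes were named by a rule set in advance. It takes up to 12 genes with the largest rise and 12 with the largest fall among called genes with a symbol whose groups do not overlap, leaving out provisional symbols, then 13 core genes of bone formation, and up to 4 members of each list with the smallest unadjusted p. The rule gave 152 measured genes, of which the text names those that passed, except 1 not reported here. Many of those that did not pass appear only in the counts of their list. Of the 152, 22 have several kept probes, and for 6 another probe has the opposite sign. A fold is given as a lower bound where the dimmer group was not above background on any of its arrays, taking the background limit as its level, or where the brighter group reached the scanner limit. No fold is taken from the spot tables for a probe at the limit on all 6 arrays.

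The slide of each array was inferred from the tilt of the scanned grid, since the labels give no slide. Control 1 and control 2 had a tilt of 0.0925 and 0.0943 micrometres per column, and control 3 and the LIPUS arrays 0.0522 to 0.0601, with standard errors of 0.00031 to 0.00035. Control 1 and control 2 were therefore taken as slide 1, and control 3 with the 3 LIPUS arrays as slide 2. Results are given with slide as a block in the fit, a fixed block unless stated otherwise, and as LIPUS minus control 3. Slide 1 holds only controls, so the change with slide as a fixed block equals LIPUS minus control 3. Both rest on the 1 control array of slide 2, and control 1 and control 2 add only to the estimate of spread.

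The alternatives were spot means, quantile normalization, median centring, the value table, no filter on dim probes, detection on all 6 arrays, replicate number as a block, each array left out in turn, slide as a fixed or random block, array weights, a variance trend with robust fitting, all probes tested separately, the mean of a gene's probes, a list mean in place of its median, an adjusted p under 0.01, lists without genes shared by several lists, and the list tests above. Scaling to spike-in controls, slide 2 alone and leaving out probes at the scanner limit were chosen after seeing the data. The pipeline was tested on simulated data with 200 changed genes among 21845: it recovered 4% of genes changed 1.5-fold, 40% at 2-fold, 94% at 3-fold and 90% at 4-fold, with 5 false calls. Camera picked up a simulated list shift of 0.5, and 0 of 100 unchanged lists had an unadjusted p under 0.05. Simulated lists need not be correlated as real ones are, and on the real arrays no list call held with an estimated correlation. For the cell cycle, endothelial, Wnt, hypoxia, osteocyte and fibrillar collagen lists the estimate (−0.107 to −0.0017) lay below the preset 0.01. A higher correlation thus cannot be why these calls were lost. For the other called lists the estimate lay above it (0.029 to 0.473).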

Results

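Rat bone marrow cells kept under osteogenic conditions were profiled on 6 single-colour arrays on day 10, 3 from control samples and 3 from samples treated with low-intensity pulsed ultrasound (LIPUS). Probes above background made up 55.1%, 53.5% and 61.3% of all probes on the control arrays and 56.3%, 55.3% and 61.9% on the LIPUS arrays. The number of probes at the scanner's upper limit was 432 ± 41.8 (SD, n = 3) in control and 350 ± 30.5 (SD, n = 3) in LIPUS (exact permutation test, two-sided, p = 0.1, the smallest possible). Median spot brightness was 218, 183 and 224 in control and 194, 163 and 161 in LIPUS. Correlations between arrays across genes, which are not independent replicates, were 0.964 to 0.986. On the leading principal component, with 46.6% of the variance, the control arrays lay at −37.9, −38.4 and −15.9 and the LIPUS arrays at 29.2, 35.2 and 27.8. The next component, with 18.4%, set control 3 apart, at −41.8 against 1.46 to 22.1 for the other arrays.

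The comparison of LIPUS with control asks which genes respond to ultrasound during osteogenic culture. The largest rise was in Cthrc1 (NM_172333), which encodes a secreted protein of bone and injured matrix: its log2 level was 0.88 ± 0.22 in control and 4.17 ± 0.21 in LIPUS (SD, n = 3 each), a 9.80-fold rise (limma adjusted p = 0.00022). Among bone cell genes, the channel gene Panx3 (NM_199398) rose 3.67-fold (log2 1.88 ± 0.17, SE) and Dmp1 (NM_203493), a matrix phosphoprotein of late osteoblasts and osteocytes, rose 3.01-fold (1.59 ± 0.15). The largest fall was in Clec10a (NM_022393), a lectin receptor of macrophages and dendritic cells, which was 7.97-fold lower (−2.99 ± 0.18, adjusted p = 0.00022). The inhibitory Fc receptor gene Fcgr2b (NM_175756) was 5.40-fold lower (−2.43 ± 0.20).

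Other large rises were in the neuropeptide gene Gal (NM_033237; log2 2.24 ± 0.17), the sialidase gene Neu3 (NM_054010; 2.23 ± 0.18), Grin3b (NM_133308; 1.94 ± 0.20), the matrix glycoprotein gene Thbs1 (NM_001013062; 1.78 ± 0.26) and the carboxypeptidase gene Cpz (NM_031766; 1.74 ± 0.18). Or1j19 (NM_001000827), Crygd (NM_033095) and Gramd2a (XM_217153) rose by 1.69 ± 0.27, 1.66 ± 0.27 and 1.59 ± 0.18. Or1j19 was above background on only 1 control array, so the size of its change is uncertain. With all probes tested separately, the other probe of Crygd read 0.73 and did not pass (limma adjusted p = 0.0656). Slc27a5 (NM_024143) was above background on no control array and all 3 LIPUS arrays, and was at least 3.29-fold higher in LIPUS. Large falls were in the nuclease gene Dnase1l3 (NM_053907; −2.66 ± 0.18), the cadherin gene Cdh1 (NM_031334; −2.57 ± 0.33), Cox6a2 (NM_012812; −2.44 ± 0.20), the stress-response gene Trib3 (NM_144755; −2.19 ± 0.20) and Arl11 (NM_001013433; −2.14 ± 0.15). Cdh1 was above background on only 2 LIPUS arrays. Slc7a3 (NM_017217) fell by 2.11 ± 0.23, P2ry12 (NM_022800) by 2.07 ± 0.23, Kcnk13 (NM_022293) by 2.06 ± 0.17 and the prostaglandin D synthase gene Hpgds (NM_031644) by 2.03 ± 0.22. These 23 genes had adjusted p values of 0.00022 to 0.00693, and each remained called whichever array was left out. With slide as a block, 20 of the 23 kept their call; Or1j19 (adjusted p = 0.141), Cdh1 (0.0874) and Slc7a3 (0.0519) did not.

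**Figure D1:**
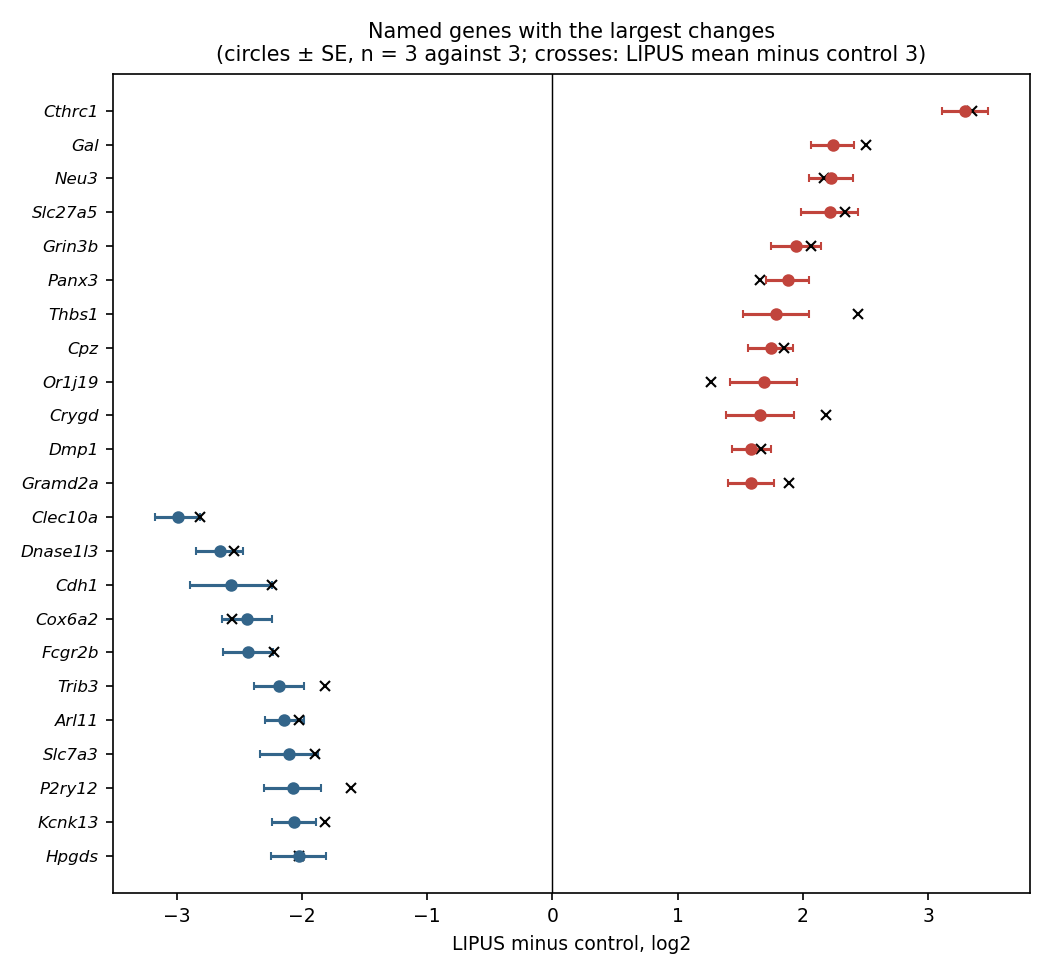
Log2 change, LIPUS minus control, of 23 named genes with large changes; circles show the estimate from 3 arrays against 3 with its standard error, and crosses the LIPUS mean minus control 3, the control array on the LIPUS slide. Cthrc1 at 3.29 and Clec10a at −2.99 lie farthest from 0. Every cross lies on the same side of 0 as its circle, as it must for genes chosen with groups that do not overlap. The circle of Slc27a5, not above background in control, is not a bound.

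Of 21845 genes and unnamed probes tested, 1449 were called, 632 higher and 817 lower in LIPUS, with a median change of 0.89 among the higher and −0.99 among the lower. Of the 495 called with a symbol, 193 were higher and 302 lower. All 1449 changed at least 1.5-fold and 608 at least 2-fold (215 higher, 393 lower). An unadjusted p under 0.05 was reached by 4826. The 2 groups did not overlap for any called gene and for 27.2% of all tested, where chance gives 10%. The control arrays lay on 2 slides, and with slide as a fixed block 282 genes were called (121 higher, 161 lower), 251 of them among the 1449 with the same direction. Slide as a random block gave 1013 calls (429 higher, 584 lower) and kept 1008 of the 1449. All 1449 had the same direction in LIPUS minus control 3, as they must, since the groups of no called gene overlap. The median ratio to the full change was 0.937, over genes chosen for that change. Slide 2 alone, with its 1 control array, gave 0 calls with limma and 3339 at an unadjusted p under 0.05. Without control 1, 2 or 3 the calls numbered 642, 786 and 2168, and without LIPUS 1, 2 or 3 they numbered 719, 652 and 792. Without control 3 the controls left and the LIPUS arrays lie on different slides, so group and slide cannot be told apart there.

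The split between higher and lower depends on the scaling. Higher genes made up 43.6% of calls with the 75th percentile, 32.3% with median centring and 5.3% with scaling to spike-in controls, which shifted the median of all genes by −0.351, from 0.03 to −0.32. Under spike-in scaling 1012 of the 1449 genes kept their call. All 1449 kept their sign, as they must when changes of at least 1.5-fold all shift by −0.351. Changes are therefore relative to the array's 75th percentile.

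Genes of osteoblast differentiation and bone matrix were higher in LIPUS, with a median log2 change of 0.51 over 24 measured members (0.16 under spike-in scaling). The mean of the list was 3.24 ± 0.03 in control and 3.89 ± 0.05 in LIPUS (SD, n = 3 each; exact permutation test, two-sided, p = 0.1). Panx3 and Dmp1 rose as above, Cgref1 (NM_139087) rose 2.80-fold (log2 1.49 ± 0.16) and Smpd3 (NM_053605), which encodes a sphingomyelinase needed for mineralization, 2.61-fold (1.39 ± 0.19), and these 4 kept their calls with slide as a block. In all, 10 members rose, 0 fell and 14 did not pass, and 12 rose when adjusted over the list alone. The list passed camera (adjusted p = 2.01e-09; adjusted p = 0.0729 with an estimated correlation), also with slide as a block (median 0.56, adjusted p = 3.91e-09) and whichever array was left out. With Msx2 at its bound the median was 0.44. Of the 24 members, 4 were at the scanner limit on all 6 arrays and read 0.24 to 0.28, mostly set by the scaling. Over the 18 members whose probes stayed under the limit on every array the median was 0.57 (camera adjusted p = 1.02e-08).

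Of the core bone genes, Ibsp (NM_012587; log2 0.53 ± 0.17, adjusted p = 0.113), Tnfrsf11b (NM_012870; 0.76 ± 0.22, 0.0706), Alpl (NM_013059; 0.34 ± 0.17, 0.290), the transcription factor gene Sp7 (NM_181374; 0.18 ± 0.22, 0.685) and the adipocyte regulator gene Pparg (NM_013124; −0.12 ± 0.15, 0.696) did not pass. Ibsp reached an adjusted p of 0.0390 without control 3, where the controls left and the LIPUS arrays lie on different slides. Without any 1 of the other arrays it was 0.183 to 0.288 in limma, and LIPUS minus control 3 was 0.26. Runx2, Col1a1 and Mmp13 have no probe with a symbol, and Ptgs2 and Tnfsf11 were too dim. Bglap (NM_013414) and Spp1 (NM_012881), which encode osteocalcin and osteopontin, were at the scanner limit on all 6 arrays. In the authors' value table, where fewer probes reach the limit, Spp1 was higher by 2.07 ± 0.14 (limma adjusted p = 0.0105). Mepe, at the limit of the spot tables on the 3 LIPUS arrays, was higher by at least 2.89 (0.00934) and Bglap by at least 1.97 (0.0136), since their signal in that table too reached 99.9% of the limit, on 1 LIPUS array for Mepe and on all 3 for Bglap. In the same table Col1a2 (0.11 ± 0.15, 0.715) did not pass, and Sparc, at the limit there on all 6 arrays, gives no estimate. Spp1 and Col1a2 were each above 90% of the limit on 1 array of that table, Col1a2 at 99.9% on control 1. Of 274 genes or probes at the limit on all 6 arrays of the spot tables, 273 lie within 0.01 of +0.24 by construction, since the 75th percentile of log2 brightness differed by −0.24 between the groups; Spp1 reads 0.28.

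**Figure D2:**
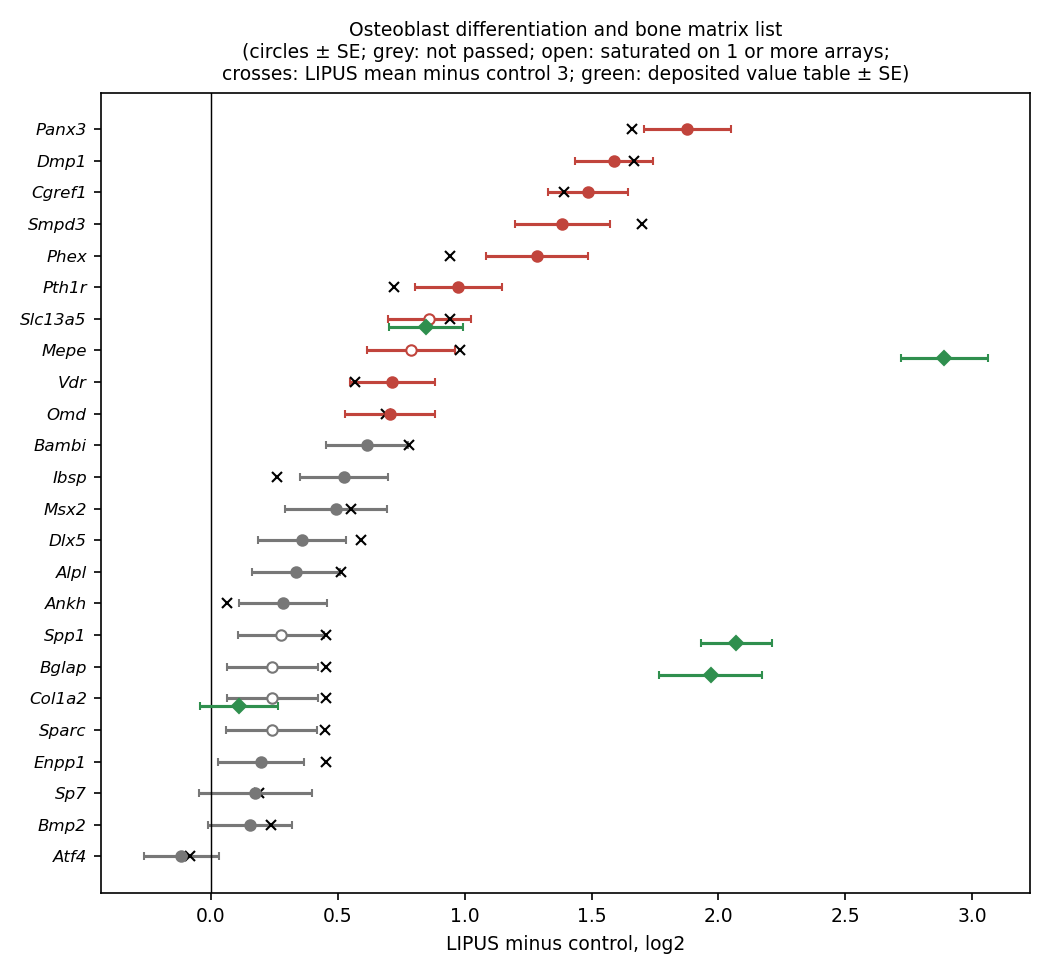
Log2 change, LIPUS minus control, of the 24 measured genes of the osteoblast and bone matrix list; circles show the spot tables with standard errors (3 arrays against 3; grey not passed, open at the scanner limit on 1 or more arrays), crosses the LIPUS mean minus control 3, and green diamonds the deposited value table with standard errors, without Sparc, which is at the limit there on all 6 arrays. Of the 24 circles, 23 lie above 0, of which 4 were at the scanner limit on all 6 arrays and are placed mostly by the scaling. The diamonds of Mepe, Spp1 and Bglap at 2.89, 2.07 and 1.97 lie far above their open circles, those of Mepe and Bglap being lower bounds.

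Osteocyte genes partly overlap with this list: of 9 measured, 5 rose, 1 fell and 3 did not pass (5 and 2 adjusted over the list alone), with a median of 0.73. Dmp1 rose, as did Phex (NM_013004; log2 1.29 ± 0.20) and the potassium channel gene Kcnk2 (NM_172041; 1.23 ± 0.24), while Capg (NM_001013086) fell by 0.82 ± 0.16. Of these 4, only Dmp1 kept its call with slide as a block. Kcnk2 lost its call without control 2, LIPUS 1 or LIPUS 3 (adjusted p up to 0.0670) and Capg without LIPUS 1 or LIPUS 2 (up to 0.0631). The camera call (adjusted p = 0.0327; adjusted p = 0.224 with an estimated correlation) ended with slide as a block (median 0.78, 0.0952), without probes at the scanner limit (0.119), without control 3 (0.0773) and without LIPUS 3 (0.0542). With genes that occur in several lists left out, the osteocyte median was 0.052 (0.573) and the test had the opposite direction.

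Macrophage and monocyte genes were lower in LIPUS. Beside Fcgr2b, the Fc receptor genes Fcgr3a (NM_207603; log2 −1.58 ± 0.16) and Fcgr2a (NM_053843; −1.37 ± 0.16) and the macrophage marker Aif1 (NM_017196; −1.54 ± 0.16) fell, and all 4 kept their calls with slide as a block and whichever array was left out. Of 20 measured members 9 fell, 1 rose (Mpeg1, 0.77 ± 0.18) and 10 did not pass, with the same counts adjusted over the list alone. Mpeg1 was not above background on the control arrays and was at least 1.37-fold higher. The list median was −0.44 over all members and −1.12 over the 13 whose probes stayed under the scanner limit on every array. Camera gave an adjusted p of 1.21e-05 (adjusted p = 0.224 with an estimated correlation), and 6.59e-06 with slide as a block (median −0.81). C1qb and Lyz2 were at the limit on all 6 arrays.

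Antigen presentation genes of MHC class II, which macrophages, dendritic cells and B cells express, had a median of −0.52 over 7 measured members, all below 0. RT1-Da (NM_001008847) fell by 0.67 ± 0.17, but its other probe read 0.24 and its call ended without any 1 of control 1, control 2 and the 3 LIPUS arrays (adjusted p = 0.0823 to 0.148). The other 6 did not pass, while 5 members fell adjusted over the list alone. Camera gave an adjusted p of 0.00241 (adjusted p = 0.224 with an estimated correlation), and 0.00571 with slide as a block (median −0.50). Endothelial cell genes had a median of −0.78 over 8 measured members, all below 0: 4 fell and 6 fell adjusted over the list alone. The list has 19 members, and Pecam1, Cdh5, Tek and Vwf were among those not measured. The adhesion gene Esam (NM_001004245) fell by 1.80 ± 0.22 and the receptor partner gene Ramp2 (NM_031646) by 1.23 ± 0.20, at adjusted p values of 0.0552 and 0.104 with slide as a block. Ramp2 was above background on only 2 LIPUS arrays. Icam2 (NM_001007725) fell by 1.05 ± 0.19 and kept its call with slide as a block (0.0360) but not without LIPUS 1 (0.0555). The endothelial list had a camera adjusted p of 6.26e-06 (adjusted p = 0.0729 with an estimated correlation), and 3.48e-06 with slide as a block (median −0.57).

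Cell cycle genes were lower in LIPUS, with a median of −0.60 over 20 measured members, of which 19 lay below 0. The cyclin gene Ccnb2 (NM_001009470) fell by 1.07 ± 0.20, Cdk1 (NM_019296) by 0.99 ± 0.20, Birc5 (NM_022274) by 0.99 ± 0.21 and Foxm1 (NM_031633), a regulator of mitotic genes, by 0.89 ± 0.20. In all 7 fell, 0 rose and 13 did not pass, and 9 fell adjusted over the list alone. Camera gave an adjusted p of 3.67e-08 (adjusted p = 0.0729 with an estimated correlation), and 3.91e-09 with slide as a block (median −0.66). None of these 4 single genes kept its call with slide as a block (adjusted p = 0.127 to 0.261). Ccnb2 remained called whichever array was left out, while the adjusted p rose to 0.0695 for Cdk1 without LIPUS 2, 0.0963 for Birc5 without control 1 and 0.0978 for Foxm1 without LIPUS 3. Cdk1 also lost its call without control 1, control 2 or LIPUS 3, Birc5 without control 2, LIPUS 1 or LIPUS 2, and Foxm1 without any 1 control array or LIPUS 2.

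**Figure D3:**
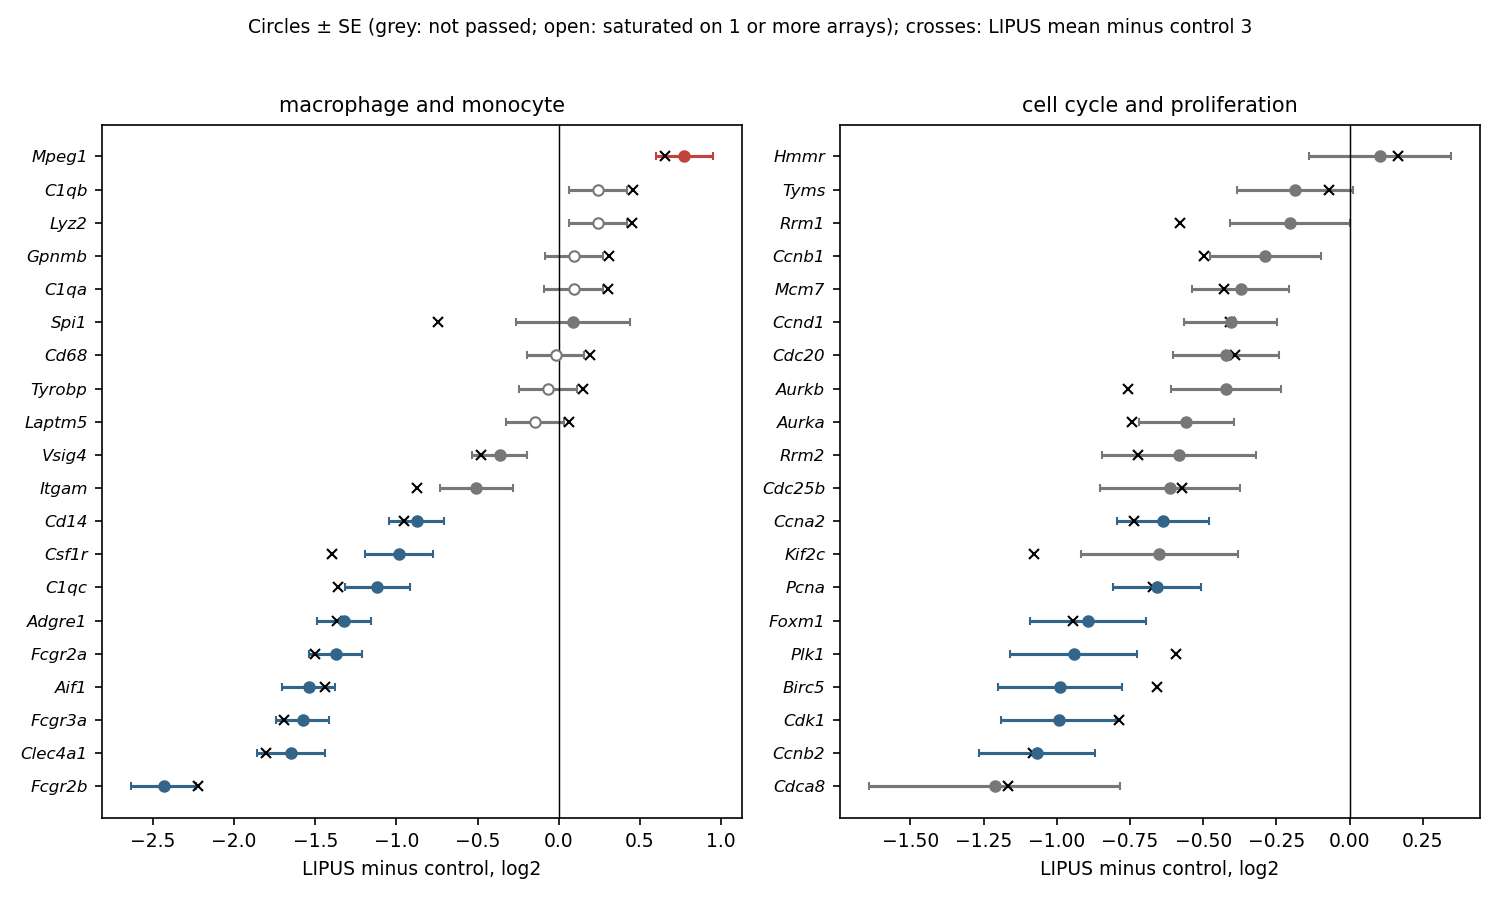
Log2 change, LIPUS minus control, of the measured genes of the macrophage and monocyte list (left, 20 genes) and the cell cycle list (right, 20 genes); circles show estimates with standard errors (3 arrays against 3; grey not passed, open at the scanner limit on 1 or more arrays) and crosses the LIPUS mean minus control 3. Macrophage genes spread from −2.43 for Fcgr2b to 0.77 for Mpeg1, which was not above background in control, so that its circle is not a bound. Of the 20 cell cycle genes, 19 lie below 0.

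Immediate early and mechanoresponsive genes, which react within minutes to hours to loading or serum, included 6 that fell and 0 that rose of 26 measured, with 20 not passed and 8 that fell adjusted over the list alone. Fos (NM_022197) fell by 1.58 ± 0.27, Jun (NM_021835) by 1.20 ± 0.20 and Egr2 (NM_053633) by 1.06 ± 0.18, each whichever array was left out, but with slide as a block their adjusted p values were 0.160, 0.107 and 0.110. The list median was −0.14, against −0.49 under spike-in scaling and −0.33 in the value table. The camera call (adjusted p = 0.0235; adjusted p = 0.315 with an estimated correlation) ended with slide as a block (median −0.11, 0.0745), in the value table (0.0644), without control 3 (0.0514) and without LIPUS 2 (0.0597).

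Wnt signalling genes had a median of 0.36 over 12 measured members, 0.01 under spike-in scaling: 3 rose, 0 fell and 9 did not pass, and 4 rose adjusted over the list alone. The receptor gene Fzd2 (NM_172035) rose by 1.05 ± 0.19, the target gene Ccn4 (NM_031716) by 0.89 ± 0.18 and Ctnnb1 (NM_053357), which encodes beta-catenin, by 0.85 ± 0.17. With slide as a block these 3 genes had adjusted p values of 0.155, 0.124 and 0.157. Fzd2 lost its call without control 1 or LIPUS 2 (up to 0.0527), Ccn4 without control 1, control 2 or LIPUS 2 (up to 0.0746) and Ctnnb1 without control 1 or any 1 LIPUS array (up to 0.0724). Camera gave an adjusted p of 0.0191 (adjusted p = 0.224 with an estimated correlation), and 0.0486 with slide as a block (median 0.60).

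Adipocyte genes had a median of 0.21 over 22 measured members, which turned to −0.15 under spike-in scaling: 3 rose, 0 fell and 19 did not pass, and 4 rose adjusted over the list alone. The lipid droplet gene Cidec (NM_001024333) rose by 1.09 ± 0.18 whichever array was left out. Scd (NM_139192) rose by 0.88 ± 0.18, though not without control 1, control 2 or LIPUS 2 (adjusted p up to 0.0780), and neither gene kept its call with slide as a block (0.124 and 0.164). The list had a camera adjusted p of 0.0195 (adjusted p = 0.315 with an estimated correlation), and 0.0167 with slide as a block (median 0.31). Chondrocyte genes had a median of 0.50 over 7 measured members, 0.15 under spike-in scaling: Col11a2 (NM_212528) rose by 1.51 ± 0.17, also adjusted over the list alone and with slide as a block (0.0369), 0 fell and 6 did not pass. The cartilage collagen gene Col2a1 (NM_012929) did not pass (1.44 ± 0.52, adjusted p = 0.140), and its other probe read −0.07. The chondrocyte camera call (adjusted p = 0.0327; adjusted p = 0.315 with an estimated correlation) ended with slide as a block (median 0.20, 0.356), without control 1 (0.125) and without LIPUS 3 (0.0689).

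Fibrillar collagen and collagen processing genes had a median of 0.24 over 11 measured members, which turned to −0.11 under spike-in scaling. That median is the reading of a probe at the scanner limit on all 6 arrays, as 3 members are, and with every probe at the limit on 1 or more arrays left out it was 0.33 over 7 members. Col5a1 (NM_134452) rose by 1.05 ± 0.18 and the lysyl hydroxylase gene Plod2 (NM_175869) by 0.82 ± 0.18, Col5a3 (NM_021760) fell by 1.14 ± 0.17, and 8 did not pass (3 rose and 1 fell adjusted over the list alone). With slide as a block the adjusted p values were 0.127, 0.162 and 0.0467. Col5a1 lost its call without control 1 (0.0508) and Plod2 without control 1, control 2, LIPUS 1 or LIPUS 3 (up to 0.0954). The camera call (adjusted p = 0.0327; adjusted p = 0.224 with an estimated correlation) ended with slide as a block (median 0.45, again the reading of such a probe, 0.124), without probes at the scanner limit (0.141), without control 1 (0.0565) and without LIPUS 2 (0.0597). Hypoxia and glycolysis genes had a median of 0.25 over 28 measured members, which turned to −0.10 under spike-in scaling: the lactate transporter gene Slc16a3 (NM_030834) rose by 1.40 ± 0.31, 0 fell and 27 did not pass, against 3 and 1 adjusted over the list alone. Slc16a3 lost its call with slide as a block (0.342) and without LIPUS 1, 2 or 3 (0.0945, 0.0549 and 0.0934). The hypoxia list passed camera (adjusted p = 0.0230; adjusted p = 0.224 with an estimated correlation) whichever array was left out, but not with slide as a block (median 0.19, 0.190).

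Ribosomal protein and other housekeeping genes had 0 members that rose or fell of 25 measured, also adjusted over the list alone, and a median of 0.24, which turned to −0.11 under spike-in scaling. Of the 25, 18 were at the scanner limit on all 6 arrays and so read 0.24 to 0.25 by construction. With every probe at the limit on 1 or more arrays left out, 5 members remained measured and the camera adjusted p went from 0.0327 to 0.498. It was 0.573 with an estimated correlation, 0.148 in the value table, and 0.00255 with slide as a block (median 0.45). That median is what a probe at the limit on all 6 arrays reads against control 3, so it gives no evidence of a change. Over members without a probe at the limit, the median of LIPUS minus control 3 was −0.05. The list lost its call without control 1 (0.102), control 3 (0.140), LIPUS 2 (0.127) or LIPUS 3 (0.0738).

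In all, camera called 13 of the 33 lists, 8 higher and 5 lower, and 8 of the 13 with slide as a fixed block. These 8 include the ribosomal protein and housekeeping list, whose median there is set by probes at the scanner limit. With slide as a random block it called 12 lists, 7 higher and 5 lower. Under spike-in scaling, the medians not given above were 0.38 for the osteocyte list, −0.79 for macrophages, −0.87 for MHC class II, −1.14 for endothelial cells and −0.95 for the cell cycle. None of the 13 calls holds with an estimated correlation, where 6 lists have an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 19 lists moved on balance one way and 30 changed in either direction.

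**Figure D4:**
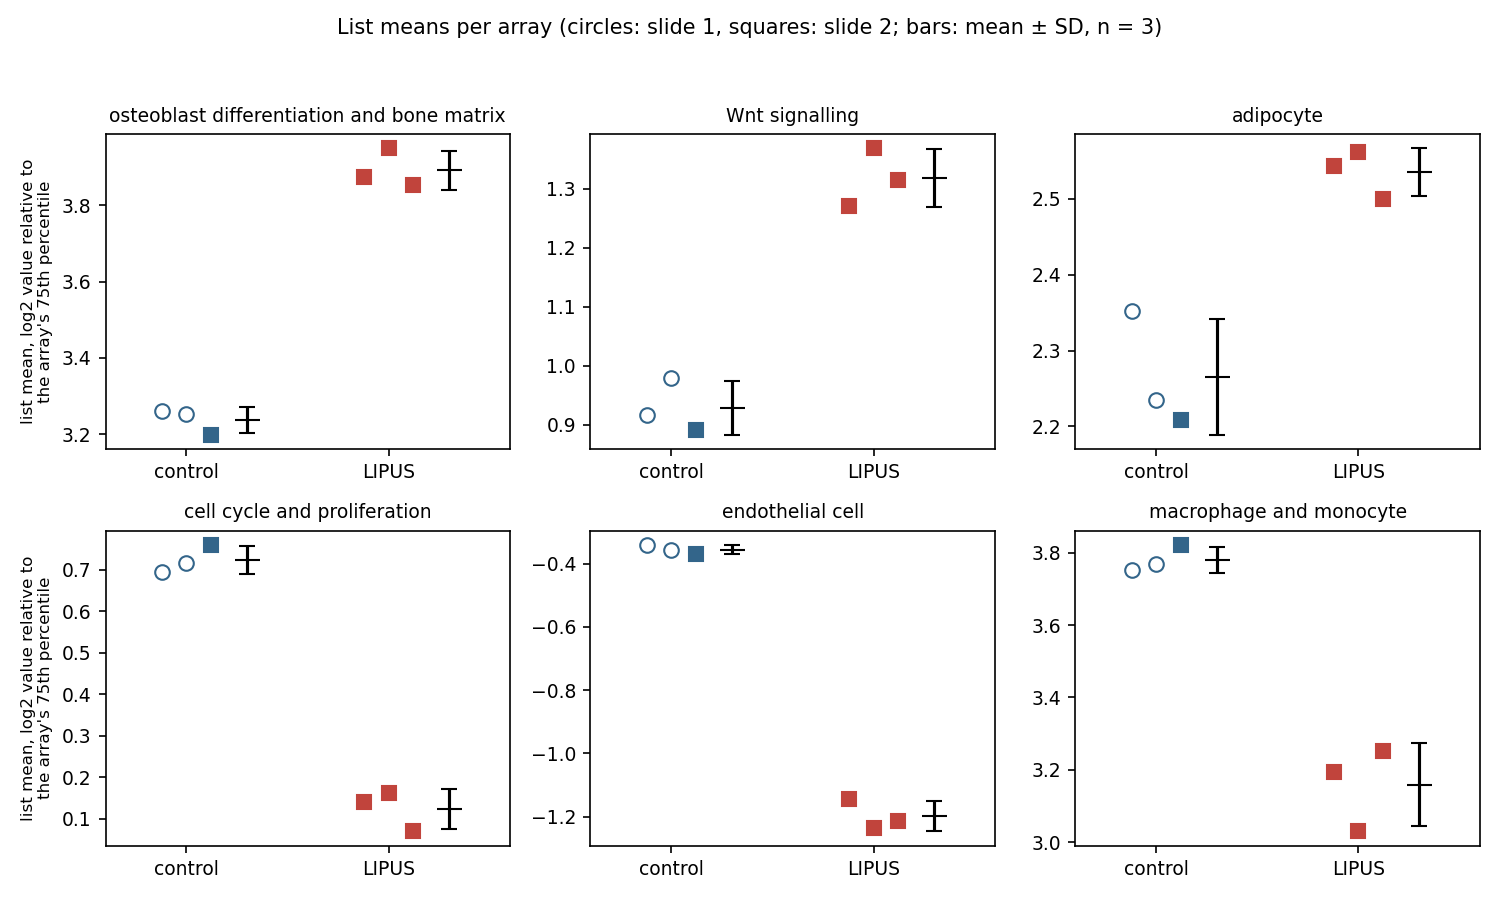
Mean of 6 gene lists on each array, in log2 units relative to the array's 75th percentile; open circles are arrays on slide 1, filled squares arrays on slide 2, and bars the mean ± SD of 3 arrays. In each panel the 3 LIPUS arrays lie on one side of the 3 control arrays, including control 3 on the LIPUS slide; under spike-in scaling the median of the adipocyte list changes sign.

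Lists of other marrow cell types did not pass camera, but many of their members were not measured. Measured were 7 of 17 osteoclast members, without Calcr, Mmp9 or Nfatc1, and 8 of 31 lymphocyte members. Of 25 erythroid and megakaryocyte members 7 were measured, with no haemoglobin gene. These lists therefore say little about whether such cells changed. For osteoclasts 0 of 7 measured members rose or fell, also adjusted over the list alone (median 0.11, adjusted p = 0.942), with Acp5 (NM_019144) at 0.23 ± 0.16 and Car2 (NM_019291) at −0.26 ± 0.16. Among 13 stromal progenitor and perivascular genes 2 fell and 0 rose (3 fell adjusted over the list alone), and the median of 0.03 differed in sign from the mean of −0.17 and the test (adjusted p = 0.218). Grem1 (NM_019282), also in the BMP and TGF-beta list, did not pass (0.41 ± 0.18). With all probes tested separately, its other probe rose by 0.97 and passed (limma adjusted p = 0.00998). Vcam1 (NM_012889), at the scanner limit in control, was at least 2.11-fold lower, and Lepr (NM_012596) fell by 0.90 ± 0.20, with adjusted p values of 0.149 and 0.194 with slide as a block. Lepr lost its call without control 1 or any 1 LIPUS array (up to 0.0966). Among 13 granulocyte and mast cell genes the mast cell protease gene Cma1 (NM_013092) fell by 1.18 ± 0.18 and S100a8 (NM_053822) rose by 0.99 ± 0.20, against 1 rise and 2 falls adjusted over the list alone; the median was 0.04, the mean −0.15 and the test was in the direction of the mean (adjusted p = 0.225). S100a8 lost its call without control 1, LIPUS 1 or LIPUS 2 (up to 0.0895), and both lost it with slide as a block (0.0956 and 0.159).

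Of 8 lymphocyte genes the adaptor gene Blnk (NM_001025767) rose by 1.08 ± 0.16 and 0 fell (1 and 1 adjusted over the list alone; median 0.33, −0.02 under spike-in scaling; adjusted p = 0.192). Of 7 erythroid and megakaryocyte genes the platelet factor gene Pf4 (NM_001007729) fell by 1.77 ± 0.17 and Gp1bb (NM_053930) rose by 0.88 ± 0.19, with the same counts adjusted over the list alone (median 0.25, −0.10 under spike-in scaling; adjusted p = 0.417). Pf4 kept its call with slide as a block (0.0267), Blnk and Gp1bb did not (0.0784 and 0.177), and Gp1bb lost it without control 1 or any 1 LIPUS array (up to 0.0988). Of 6 smooth muscle and myofibroblast genes 0 passed, with 1 rise and 1 fall adjusted over the list alone (median 0.19, −0.16 under spike-in scaling; adjusted p = 0.754): Tpm1 (NM_001034069) was at 0.51 ± 0.15, with another probe at −0.11, and Actg2 (NM_012893) at −0.55 ± 0.18.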

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

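This comparison of spike-in controls was chosen only after the arrays had been examined. The mean log2 level of the spike-in control spots, relative to the 75th percentile of each array, was 1.66, 1.75 and 1.73 in control and 1.95, 2.29 and 1.96 in LIPUS, a difference of 0.351 (exact permutation test, two-sided, p = 0.1, the smallest possible for 3 arrays against 3). It stood out because the signal lies outside the gene probes and all 3 LIPUS arrays lay above all 3 control arrays; no explanation was tested.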

How the results depend on the processing

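Spike-in scaling, slide 2 alone and leaving out saturated probes were chosen only after the data were seen; the other tests were planned. The 1449 calls (632 higher, 817 lower) became 809 (290 and 519) in the value table, 655 (242 and 413) with no filter on dim probes, where 39143 probes were tested, 490 (163 and 327) at an adjusted p under 0.01, a stricter threshold, and 282 (121 and 161) with slide as a fixed block. They became 2424 (1120 and 1304) with array weights and 2348 (1036 and 1312) with a variance trend and robust fitting. Spike-in scaling gave 3719 (197 higher, 3522 lower), as it moves the median of all genes by −0.351. Slide 2 alone, with 4 arrays, gave 0 in total, 0 higher and 0 lower with limma, and 3339 at an unadjusted p under 0.05. Leaving out 1 array gave 642 to 2168 calls, 228 to 913 higher and 387 to 1255 lower. The largest came without control 3 (2168), where group and slide cannot be told apart. The others were 642 and 786 without control 1 and 2, and 719, 652 and 792 without LIPUS 1, 2 and 3. The replicate numbers do not pair the arrays: deviations from the group mean correlated at 0.0011, 0.0095 and −0.012, and the replicate block gave 1172 calls and kept 1097 of the 1449. Among the alternatives with 1 value per gene, all but spot means (1448) and the value table (1412 of 1449) left the sign of every tested gene among the 1449 as it was. The sign could not change with an array left out, slide as a fixed block or slide 2 alone, since the groups of no called gene overlap. Nor could it with spike-in scaling or median centring, which shift all changes by one amount smaller than 1.5-fold. No gene was called in the opposite direction. The 13 shifted lists (8 higher, 5 lower) became 8 (4 higher) with slide as a fixed block, 7 (3 higher) on slide 2 alone, and 0, with 0 higher and 0 lower, with an estimated correlation, where 6 have an unadjusted p under 0.05. The 4 higher with slide as a fixed block include the housekeeping list, whose median there is set by probes at the scanner limit. Lists higher were 4 with spot means, 5 with quantile normalization and 5 without saturated probes, and lists lower were 8 by fry. Leaving out 1 array gave 10 to 15 lists, 5 to 8 higher and 4 to 7 lower, and 8 of the 13 were called whichever array was left out. The osteocyte list reversed, at a median of 0.052 (adjusted p = 0.573), with genes in several lists left out, which removes the members shared with the osteoblast list. The osteoblast median of 0.51 stayed above 0, from 0.16 with spike-in scaling to 0.74 in the value table, and 0.46 to 0.60 with 1 array left out. Of 96 called genes given by the naming rule, 58 remained called whichever array was left out. Where no cause is given, the cause was not tested. Signal over background limits the dim end, since 53.5% to 61.9% of probes exceeded it, and saturation the bright end, where 319 to 468 probes per array reached the limit.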

Other observations

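Tests of regrouped arrays for genes, of the overall scaling, of a single loss of macrophages and of a lower macrophage share were chosen only after the result was seen, and the 73 gene families were too; the other tests were planned. Growth factor and angiogenesis genes went both ways: 4 rose and 3 fell of 24 measured (6 and 4 adjusted over the list alone), and the median of 0.03 differed in sign from the mean of −0.0017 and the camera test (adjusted p = 0.942). Igfbp3 (NM_012588) fell by 1.30 ± 0.19 and kept its call with slide as a block (limma adjusted p = 0.0380), while Igf1 (NM_178866), at the scanner limit in control, was at least 2.38-fold lower (0.0839 with the block). Prostaglandin genes also went both ways, with 2 rises and 2 falls of 10 measured, also adjusted over the list alone (median 0.02, but mean −0.06 and a test in the direction of the mean, adjusted p = 0.754). The thromboxane synthase gene Tbxas1 (NM_012687) fell by 1.46 ± 0.15 (0.0260 with the block), and Ptges (NM_021583) rose by 0.79 ± 0.18 (0.208). Ptges lost its call without control 1, control 2, LIPUS 1 or LIPUS 2 (adjusted p up to 0.113). Among 17 mechanosensitive channel and purinergic receptor genes 4 rose and 1 fell (5 and 3 adjusted over the list alone; adjusted p = 0.171): the calcium channel gene Trpv4 (NM_023970) rose by 1.22 ± 0.18 and P2ry6 (NM_057124) fell by 1.21 ± 0.17 (0.0875 and 0.0606 with the block). Of 16 proteoglycan and adhesive matrix genes 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.192), with Lum (NM_031050) at 1.10 ± 0.19 and Fbn1 (NM_031825) at −1.33 ± 0.19 (0.147 and 0.0874 with the block). With all probes tested separately, the other probe of Fbn1 read −0.59 and did not pass (limma adjusted p = 0.116).

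Stress genes mostly did not pass. Of 25 heat shock and unfolded protein genes 3 fell, also adjusted over the list alone, and 0 rose (adjusted p = 0.0750, and 0.0283 without control 2); Ddit3 (NM_024134) fell by 0.94 ± 0.15, and Hspa1a (NM_031971) fell by 0.86 ± 0.18 while its other probe read 0.63. Hspa1a lost its call without control 1, control 2, LIPUS 2 or LIPUS 3 (up to 0.0953). Of 21 oxidative stress genes 1 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.0870, and 0.0426 without control 2): Gstp1 (NM_012577) fell by 1.40 ± 0.15 and Hmox1 (NM_012580) by 1.29 ± 0.16, both called with the block (0.0313 and 0.0383). Of 18 glucocorticoid response genes 1 rose and 2 fell, with the same counts adjusted over the list alone (median 0.03, but mean −0.06 and a test in the direction of the mean, adjusted p = 0.679), with Glul (NM_017073) lower by a log2 change of −1.11 ± 0.17. Of 21 chemokine and cytokine genes 2 rose and 4 fell (4 and 7 adjusted over the list alone; adjusted p = 0.192), with Ccl2 (NM_031530) at −1.55 ± 0.24. Of 13 interferon genes 2 fell, also adjusted over the list alone (adjusted p = 0.171), with Psmb9 (NM_012708) at −1.31 ± 0.18. Of 18 matrix protease and inhibitor genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0876), with Timp1 (NM_053819) at least 1.77-fold higher, a call lost without control 1, LIPUS 2 or LIPUS 3 (up to 0.0659). Of 29 BMP and TGF-beta genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.175), with Bmp3 (NM_017105) at 0.92 ± 0.16, a call lost without LIPUS 2 (0.0501). With slide as a block, Ddit3, Hspa1a, Glul, Ccl2, Psmb9, Timp1 and Bmp3 had adjusted p values of 0.0558 to 0.187, and none kept its call. Of 21 sterol synthesis genes 1 fell (2 adjusted over the list alone; adjusted p = 0.175). Of 13 integrin and focal adhesion genes (adjusted p = 0.151, and 0.0426 in the value table) and 22 oxidative phosphorylation genes (adjusted p = 0.731) none passed in limma, also adjusted over the list alone. Camera on 73 gene families by symbol shifted 0 of them, with 10 at an unadjusted p under 0.05 and a lowest adjusted p of 0.117. With slide as a block 3 families passed: Rpl (median 0.45, adjusted p = 0.000223) and Rps (0.45, 0.00685), which hold mostly ribosomal proteins, and Clec (−0.52, 0.00685), which holds Clec10a. The median of 0.45 is what a probe at the scanner limit on all 6 arrays reads against control 3, so it gives no evidence of a change. With an estimated correlation and no block, the adjusted p of these 3 families was 0.926, 0.926 and 0.871.

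The other genes given by the naming rule that passed were 9 rises and 11 falls. Rises were in Smad9 (NM_138872; log2 1.45 ± 0.29), Fgfr1 (NM_024146; 1.21 ± 0.22), Gpx3 (NM_022525; 0.96 ± 0.22), Mmp16 (NM_080776; 0.95 ± 0.18), Aspn (NM_001014008; 0.95 ± 0.19), Csf1 (NM_023981; 0.87 ± 0.17), Mmp2 (NM_031054; 0.84 ± 0.17), Ptgis (NM_031557; 0.79 ± 0.18) and Angptl4 (NM_199115; 0.64 ± 0.16). Falls were in Egr1 (NM_012551; −1.31 ± 0.27), Ccl6 (NM_001004202; −1.24 ± 0.19), Mt1 (NM_138826; −1.12 ± 0.20), Il18 (NM_019165; −1.08 ± 0.18), Pla2g4a (NM_133551; −0.89 ± 0.18), Igfbp4 (NM_001004274; −0.88 ± 0.18), Inhba (NM_017128; −0.85 ± 0.21), Adamts5 (NM_198761; −0.82 ± 0.17), Cldn5 (NM_031701; −0.72 ± 0.15), Tm7sf2 (NM_001013071; −0.70 ± 0.15) and Gbp2 (NM_133624; −0.70 ± 0.15). Their limma adjusted p values were 0.00474 to 0.0456. With slide as a block only Csf1 kept its call (0.0453, against 0.0558 to 0.295), and only Ccl6, Il18 and Mt1 kept theirs whichever array was left out. With all probes tested separately, the other probes of Csf1 and Igfbp4 read 0.39 and −0.67 and did not pass (limma adjusted p = 0.266 and 0.0854).

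The osteoblast list was higher in LIPUS by camera at its preset correlation, but not with an estimated one (adjusted p = 0.0729, and 0.145 with slide as a block). Against a slide difference, its median of LIPUS minus control 3 was 0.559 (SE 0.101 over members), which rests on the 1 control array of that slide. It is the same change as with slide as a fixed block, so they are not separate checks. A shift of all genes by the scaling would leave the list at the median of all genes, but its median lay 0.476 above. The SE over members, 0.108, is that of their mean change and not of the median. A lower share of macrophages alone was predicted to raise the markers of all other cells alike. The osteoblast median lay 0.423 (SE 0.125) above that of 91 markers of other cell types. These pool lists that differ, with medians from −0.78 for endothelial cells to 0.50 for chondrocytes (adipocytes 0.21, stromal progenitors 0.03). A loss of some of these cells with the macrophages was not tested, so the comparison cannot decide. More osteoblasts, more transcript per osteoblast and a lower share of other cells all stay open, and an effect of LIPUS may act through any of them. A difference between cultures stays open too.

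The macrophage and cell cycle lists were lower in LIPUS by camera at its preset correlation, but not with an estimated one (adjusted p = 0.224 and 0.0729, and 0.438 and 0.145 with slide as a block). On the LIPUS slide the macrophage median was −0.808 (SE 0.204) and the cell cycle median −0.664 (SE 0.0722) against control 3. This speaks against a slide difference, but it rests on the 1 control array of that slide, and the SEs are over list members. That array, control 3, had the lowest array weight, 0.427 against 0.921 to 1.59 for the others. A single loss of macrophages was predicted to lower every marker by one factor. Over the 13 unsaturated members, Cochran's Q over its degrees of freedom was 18.6, a ratio of variances about 1 for equal changes. The 13 include Mpeg1, not above background in control, and no value without it was computed. Probe background and expression in other cells can make the measured changes unequal after a single loss too, so this cannot decide against one. A single loss of macrophages and a change in macrophage state, with or without fewer cells, both stay open, and slower division stays untested. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called genes and 1 as many lists, the real one: 1449 genes against at most 0 in the others, which had 463 to 1281 at an unadjusted p under 0.05 in limma, and 13 lists against at most 6; these splits are too few for a share under 0.05.

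Bone matrix genes at the scanner's upper limit may have changed more than the spot tables can show. For the 6 osteoblast list genes at the limit on 1 or more arrays, the size of the log2 change in the value table exceeded that in the spot tables by a median of 0.982 (SE 0.417), which lies between the values of Sparc and Bglap and so is no measure of size. A probe at the limit on all 6 arrays reads 0.48 in the value table and 0.24 in the spot tables by scaling alone, and Sparc is such a probe in both. With Sparc left out and this difference taken off, chosen after seeing the values, the value table gave the larger change in 3 of 5 genes, Mepe, Spp1 and Bglap, with Mepe and Bglap as lower bounds. Col1a2 (0.11 against 0.24) and Slc13a5 (0.85 against 0.86) showed no excess.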
